A study of Mus musculus with 16 samples.

How the data were processed

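Total RNA from mouse hearts was sequenced in 16 libraries on the BGISEQ-500, per the labels' protocols. Each library belonged to 1 of 4 groups named in its title: 3 Vehicle SHAM, 4 NR SHAM, 4 Vehicle TAC and 5 NR TAC. The titles give no other replicate label than a library number, and nothing states whether libraries came from separate animals, so p-values may measure only the spread between these libraries.

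Reads were processed with TopHat, HTSeq and DESeq on GRCm38, per the submitters' processing notes, which state no versions. The 4 deposited tables hold 1 comparison each. Their signal columns are group means of counts divided by size factors, per the file headers and the values, with size factors set within each pair of groups. Means of 1 group in 2 tables therefore differ by a nearly constant factor, for example a median ratio of 1.09 for Vehicle SHAM. The deposited fold is the ratio of the means, each plus 1, and the deposited log2 value is its logarithm; both were recomputed and matched to rounding. The deposited p-value is the authors' test of the pair, and the deposited adjusted p equals the Benjamini-Hochberg adjustment over all genes of that table. Fold changes on this scale understate changes of low genes. Levels set side by side from different tables were not tested against each other. Means are given as the authors' values, without SD or n. No value per library is given, and the depth of each library is not given in the tables used here, so no counting interval is given. Counts per library had been solved from the decimals of the group means earlier in the work, and library totals, marker genes and limma fits of them were seen. They were set aside because the tables deposit group means only, and no value from them enters the results; they first drew attention to the liver, atrial, adipocyte and clock genes.

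Pairs of groups were not tested again gene by gene here: a gene was called when the authors' adjusted p was below 0.05. The plan for libraries with counts could not be applied to group means, and the plan's provision for comparison tables was followed. Groups of genes were tested with cameraPR in limma 3.58.1 under R 4.3.3, on normal quantiles of the authors' p-values carrying the sign of the fold change, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 32 lists fixed before the data were examined. A correlation could not be estimated from group means, so the preset value of 0.05 was the stricter alternative. The p-values of lists and Reactome sets take genes as the units and do not measure the spread between libraries. A list of 22 hepatocyte markers was written after its pattern had been seen and was tested outside that family. Reactome sets of 15 to 500 genes were tested with fgseaMultilevel in fgsea 1.28.0, ranked by the sign of the fold change times −log10 of the authors' p-value. Symbols were matched to gene identifiers through a reference table, which covered 18585 of 20540, 18729 of 20946, 19188 of 21420 and 18010 of 19917 genes in the vehicle TAC, NR TAC, NR against vehicle TAC and NR against vehicle SHAM tables. A symbol on more than 1 gene was kept for the gene of the higher mean.

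The difference of the NR effect between TAC and SHAM hearts was an approximate z: the difference of the 2 log2 fold changes over the root of their summed squared errors, each error being the fold change over the normal quantile of its p. It left out 1085 genes whose error could not be formed. On simulated data with 200 changed genes and a dispersion of 0.1, over 19105 genes, that test found 2% of 2-fold and 57% of 4-fold changes, with 1 false call. Correlations across genes of the fold changes that share the Vehicle TAC libraries were set beside 100 simulated draws of unchanged groups, with spreads taken from the authors' p-values in 50 bins of mean level; the simulated spread is approximate.

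Named genes followed a rule fixed before the data were examined: the 6 largest rises and 6 largest falls among called genes with a mean of at least 50 and a symbol that is not a predicted model; up to 3 called members of each passing list; up to 4 called members of the short-chain dehydrogenase/reductase and NAD metabolism lists; and Nppa, Nppb, Myh7, Myh6, Nmrk2, Nampt and Dhrs7c always. Where no gene was called, the 3 and 3 with the smallest p were named; the same limits on mean and symbol were applied there. For TAC in NR hearts, 1 gene that this rule names is not reported here. Other genes given as values were chosen after their values were seen. Positions are from GENCODE for GRCm38. Alternatives changed the threshold, a minimum mean of 10 or 50, a minimum fold, the preset correlation, ranks in place of quantiles, and the ranking and size of the Reactome sets. Leaving out the 278 genes at least 8-fold higher in Vehicle TAC than in both Vehicle SHAM and NR TAC was added after the data had been seen.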

Results

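Gene expression was measured by RNA sequencing in hearts of mice after sham surgery or TAC, the field's usual abbreviation for transverse aortic constriction, which loads the left ventricle with pressure. Hearts received vehicle or NR, a treatment the series title places among means of raising NAD+. The 16 libraries formed 4 groups: 3 Vehicle SHAM, 4 NR SHAM, 4 Vehicle TAC and 5 NR TAC. The authors' deposited tables give group means and 1 DESeq test per pair of groups, so the spread between libraries enters only through their p-values.

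The first comparison asked what TAC changed without NR. In the authors' deposited table, Acta1, the skeletal alpha-actin that the stressed heart re-expresses, rose from a mean of 11815 to 116439 normalized counts (log2 fold change 3.30, DESeq adjusted p 0.0264). Tbx15, a T-box transcription factor, rose by 2.57 and Ccdc136 by 1.46 in the authors' deposited table. Ano10, a membrane protein of the anoctamin family, fell from 2787 to 1390 (DESeq adjusted p 0.000176), and mt-Atp6, a mitochondrially encoded subunit of ATP synthase, fell by 1.01 in the authors' deposited table. Acta1 lies on chromosome 8 from 123891769 to 123894751 of GRCm38, and Ano10 on chromosome 9 from 122175874 to 122294423. The other calls in the authors' deposited table were Fjx1 (2.09), Gm45897 (2.95), Gm35533 (1.27), Gm44769 (−1.66) and Gm4076 (−1.03), named after their values were seen.

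As a group, the 16 cardiac stress genes shifted up in vehicle hearts after TAC (median log2 fold change 1.14, list adjusted p 3.8e-16); 1 of them rose over all genes tested and 11 rose adjusted over the list alone. All 45 extracellular matrix and fibrosis genes had positive fold changes (median 1.09, list adjusted p 8.0e-18), although 0 passed singly in DESeq or adjusted over the list alone (9 at an unadjusted p below 0.05). Fatty acid oxidation, the main fuel pathway of the heart, shifted down (33 of 34 negative, median −0.37, list adjusted p 8.1e-21; 3 fell adjusted over the list alone), as did the tricarboxylic acid cycle (26 of 26 negative, median −0.22) and the 13 mitochondrially encoded genes (median −0.42, 1 fell and 4 adjusted over the list alone). Immediate early genes shifted up (15 of 16 positive, median 0.30, list adjusted p 0.000268, with 0 called and 2 rising adjusted over the list alone). Heat shock genes shifted up as well (median 0.22, list adjusted p 0.0435 with a preset correlation of 0.05). Interferon response genes did not pass (list adjusted p 0.626 with that preset correlation). Contraction and calcium handling genes shifted down (19 of 28 negative, median −0.18; 0 called, 1 fell adjusted over the list alone). Macrophage markers (19 of 20 positive, median 0.62, list adjusted p 9.4e-05), fibroblast markers (median 0.42, list adjusted p 0.00873) and blood markers (12 of 12 positive, median 1.30) shifted up beside the matrix genes. Adipocyte markers shifted down (median −1.75). The 22 hepatocyte markers had a median of 8.34. Nppa, which encodes a natriuretic peptide, had means of 4661 and 49249 (DESeq adjusted p 0.939), and Nppb a log2 fold change of 1.78 (0.583), in the authors' deposited table, and neither passed. Likewise Myh7 (0.86), Myh6 (−0.29), Nmrk2 (2.87), which makes an NAD+ precursor from nicotinamide riboside, Nampt (−0.39) and Dhrs7c (−0.50) did not pass in the authors' deposited table. Short-chain dehydrogenases/reductases, the family named in the series title, did not pass as a list (42 of 66 positive, list adjusted p 0.421), nor did NAD metabolism (0.198).

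Over 20540 genes the authors' deposited table called 10 at a DESeq adjusted p below 0.05, 6 up and 4 down, and a threshold of 0.01 left 3. An unadjusted p below 0.05 was found for 1005 genes, not more than the share of 0.05 that unchanged genes would give. Of the 32 lists, 17 passed, and 13 with a preset correlation of 0.05; those lost were mitochondrial biogenesis regulators (adjusted p 0.0562), the integrated stress response (0.0565), lymphocyte markers (0.108) and adipocyte markers (0.088). Reactome sets passing numbered 71 of 743, led by extracellular matrix organization (normalized enrichment score 2.26) and, downward, the citric acid cycle and respiratory electron transport (−2.68); 41 passed when ranked by fold change among genes with a mean of at least 10, and 43 without the 278 genes at least 8-fold higher in Vehicle TAC than in both Vehicle SHAM and NR TAC.

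The second comparison asked the same of hearts that received NR. In the authors' deposited table, Acta1 rose from 10548 to 64157 normalized counts (log2 fold change 2.60, DESeq adjusted p 6.2e-05). Hspa1a, an inducible HSP70 chaperone, rose by 2.51 and the growth factor gene Fgf6 by 2.50 in the authors' deposited table. The transcription factor gene Pou3f1 (2.28) and Nlrc3 (2.00) also rose in the authors' deposited table. Among called genes with a mean of at least 50 and a symbol that is not a predicted model, the largest falls were of Mylk4, a myosin light chain kinase (−1.27), Plekhh1 (−1.15), the orphan receptor gene Gpr22 (−1.12), Ky (−1.11), Ly75 (−1.06) and Kbtbd13 (−1.05), from the authors' deposited table. Nmrk2 rose by 1.43 (DESeq adjusted p 0.000253) in the authors' deposited table.

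Immediate early genes, which respond within minutes to stimuli, shifted up in NR hearts after TAC as they did in vehicle hearts (16 of 16 positive, median 0.92, list adjusted p 1.7e-18), and 4 rose (11 adjusted over the list alone), among them Egr1 (1.30), Egr2 (1.93) and Klf4 (0.72) in the authors' deposited table. Heat shock genes (13 of 13 positive, median 0.50, list adjusted p 5.3e-12, 1 rose and 6 adjusted over the list alone) and interferon response genes (25 of 27 positive, median 0.30, list adjusted p 0.000545, 0 called or passing adjusted over the list alone) shifted up too. The NR SHAM group they are set against was itself below Vehicle SHAM in most immediate early (13 of 16), heat shock (12 of 13) and interferon response genes (27 of 27). Cardiac stress genes also shifted up (16 of 16 positive, median 0.73, 3 rose and 12 adjusted over the list alone), with Ankrd1 rising by 1.29 and Ctgf by 1.56 in the authors' deposited table. Extracellular matrix genes shifted up (44 of 45 positive, median 0.68, list adjusted p 9.1e-21, 1 rose and 6 adjusted over the list alone), and Meox1 rose by 1.11 in the authors' deposited table. Contraction and calcium handling genes shifted down (24 of 28 negative, median −0.22, 3 fell and 9 adjusted over the list alone), and the channel genes Kcnv2 (−0.86) and Kcnj2 (−0.66) and the sodium-calcium exchanger gene Slc8a1 (−0.55) fell in the authors' deposited table. Fatty acid oxidation shifted down (32 of 34 negative, median −0.29, 1 fell and 12 adjusted over the list alone), with a fall of Slc27a1, a fatty acid transporter (−0.56), and the branched-chain amino acid list shifted down with a fall of Ppm1k (−0.50) in the authors' deposited table. Nppa (3.21, DESeq adjusted p 0.203), Nppb (1.80, 0.0711), Myh7 (0.56), Myh6 (−0.33), Nampt (−0.28) and Dhrs7c (−0.37) did not pass in the authors' deposited table. Short-chain dehydrogenases/reductases (32 of 60 negative, median −0.04, mean 0.01, list adjusted p 0.177) and NAD metabolism (21 of 31 negative, median −0.08, mean 0.01, list adjusted p 0.567) did not pass as lists. In each the mean lay opposite in sign to the median and the test. Fibroblast (15 of 15 positive, median 0.34, list adjusted p 3.9e-06), macrophage (20 of 20 positive, median 0.94) and blood markers (12 of 12 positive, median 0.75) shifted up beside the matrix genes. Atrial markers shifted up in the same comparison (11 of 11 positive, median 3.02, list adjusted p 1.5e-05), as did adipocyte markers (median 1.36), and the 22 hepatocyte markers had a median of −2.83. Nppa is a member of both the atrial and the cardiac stress list, so its rise cannot be assigned to either.

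Over 20946 genes the authors' deposited table called 115 at a DESeq adjusted p below 0.05, 64 up and 51 down. Of these, 40 had an absolute log2 fold change of at least 1, and 37 passed 0.01. An unadjusted p below 0.05 was found for 1461 genes, more than the share of 0.05 that unchanged genes would give. Lists passing numbered 21, and 17 with a preset correlation of 0.05; those lost were the mitochondrially encoded genes (adjusted p 0.0554), glycolysis (0.113), the integrated stress response (0.124) and mesothelium (0.0809). Of 737 Reactome sets, 69 passed, and 27 when ranked by fold change among genes with a mean of at least 10.

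**Figure D1:**
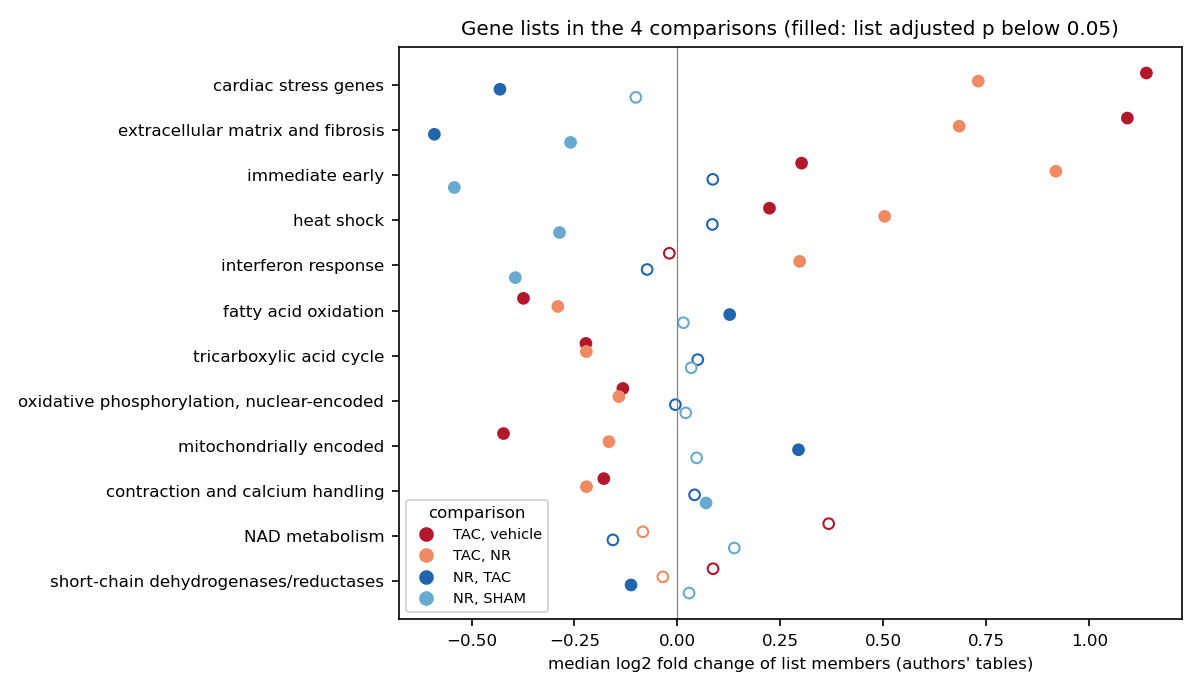
Median log2 fold change of the members of 12 of the 32 gene lists in the 4 comparisons, from the authors' deposited tables; filled points are lists with an adjusted p below 0.05, open points are not. Extracellular matrix genes lie at 1.09 and 0.68 after TAC and at −0.59 for NR in TAC hearts. The 1.09 and the −0.59 come from comparisons that share the Vehicle TAC libraries.

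The TAC effects with and without NR, which share no library, were then set against each other. Genes called in NR hearts had the same sign in vehicle hearts in 115 of 115 cases, 75 of them with an unadjusted p below 0.05 there, and 4 were called in both (Acta1, Ano10, Tbx15 and Ccdc136). The ratio of the vehicle to the NR log2 fold change over these genes had a median of 0.961, with quartiles of 0.674 and 1.18. Across 19772 genes, which are not independent replicates, the fold changes correlated weakly (Pearson r 0.077, Spearman rho 0.369). Among the 121 genes called in either comparison r was 0.874; with a mean of at least 50 it was −0.034 (rho 0.593), and without the 278 genes 0.348.

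**Figure D2:**
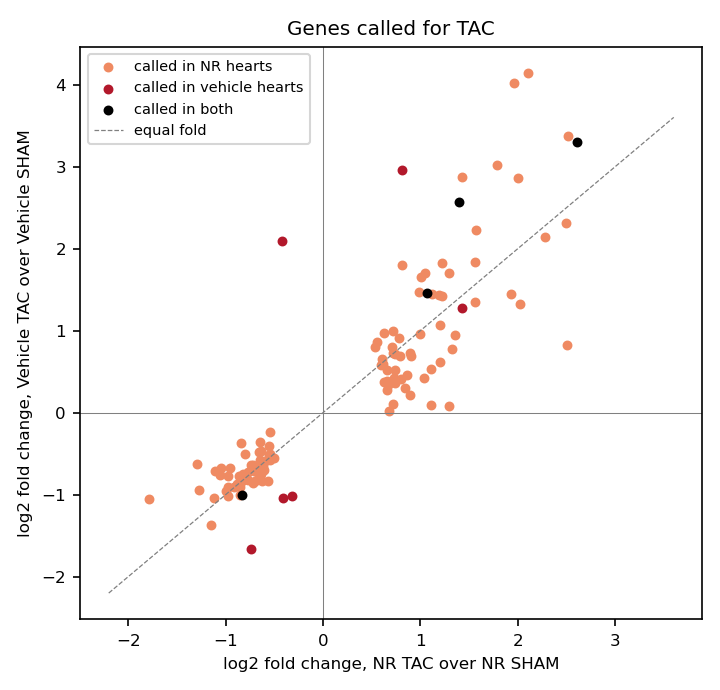
Log2 fold change for TAC in NR hearts (x axis) and vehicle hearts (y axis) for the 121 genes called in either, from the authors' deposited tables; colours show where each was called and the dashed line marks equal folds. All 115 genes called in NR hearts have the same sign on both axes.

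The third comparison asked what NR changed in TAC hearts. Extracellular matrix genes shifted down (44 of 45 negative, median −0.59, list adjusted p 9.5e-15), as did cardiac stress genes (13 of 16 negative, median −0.43, list adjusted p 0.00076), although 0 members passed singly in DESeq or adjusted over the list alone (5 and 4 at an unadjusted p below 0.05). Mitochondrially encoded genes shifted up (11 of 13 positive, median 0.29, list adjusted p 4.5e-07). So did fatty acid oxidation (29 of 34 positive, median 0.13) and the circadian clock (median 0.31, list adjusted p 0.00076). The Vehicle TAC libraries also enter the TAC effect in vehicle hearts, so list shifts opposite to that effect may come partly from those libraries. Among genes with a mean of at least 50 and a symbol that is not a predicted model, the smallest p-values of each sign in the authors' deposited table belonged to Herpud1, an endoplasmic reticulum stress gene (0.72, unadjusted p 5.6e-05), Etfbkmt (0.71) and Noct (0.63), and to Blk (−0.96), Aplnr (−0.88) and Colq (−0.86), which did not pass. Nmrk2 (−2.31), Nampt (0.38), Nppa (−0.79), Nppb (−0.73), Myh7 (−0.30), Myh6 (0.06) and Dhrs7c (0.17) did not pass in the authors' deposited table.

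Short-chain dehydrogenases/reductases shifted down with NR in TAC hearts (45 of 65 negative, median −0.11, list adjusted p 0.0241), with 0 called. The list adjusted p was 0.303 with a preset correlation of 0.05, and 0.285 without the 278 genes, 6 of which are members. NAD metabolism (18 of 32 negative, list adjusted p 0.0886), interferon response (0.929), immediate early (0.659) and heat shock genes (0.929) did not pass. Without the 278 genes, 5 of which are NAD metabolism members, that list had an adjusted p of 0.436 and a median of 0.01. Those genes were chosen partly by their fall in this comparison, so the list shift had to weaken. No list was tested for a difference of the NR effect between TAC and SHAM hearts. Hepatocyte markers had a median of −9.24 in the same comparison and of 8.34 for TAC in vehicle hearts; Alb, the plasma protein albumin, had means of 25.1 in Vehicle SHAM and 24938 in Vehicle TAC in the authors' deposited table (unadjusted p 0.0733). Atrial markers (10 of 11 positive, median 1.58) and adipocyte markers (median 0.48) shifted up, while lymphocyte markers (median −0.52) and cell cycle genes (median −0.46) shifted down.

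Over 21420 genes the authors' deposited table called 0 at a DESeq adjusted p below 0.05. An unadjusted p below 0.05 was found for 558 genes, fewer than the share of 0.05 that unchanged genes would give. What size of change the authors' test of this pair could find was not simulated, so 0 calls do not show that NR had no effect. Lists passing numbered 10, and 8 with a preset correlation of 0.05, the other list lost being the cell cycle (adjusted p 0.0521). Of 746 Reactome sets 83 passed, 7 up and 76 down, led by cytochrome P450 enzymes (normalized enrichment score −2.69), which act mainly in liver; 43 passed when ranked by fold change among genes with a mean of at least 10.

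**Figure D3:**
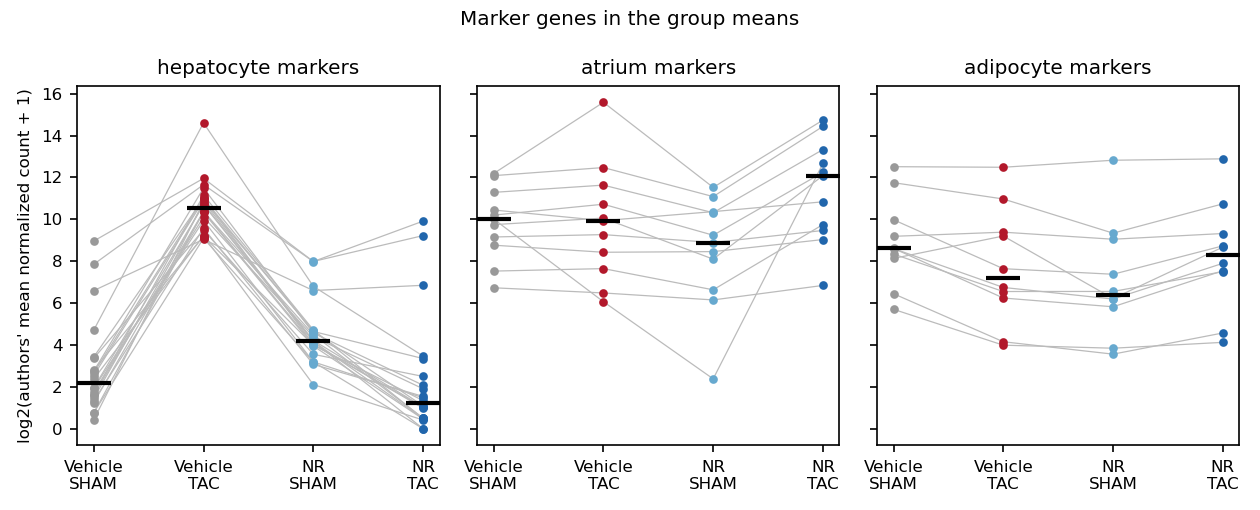
Log2 of the authors' mean normalized count plus 1 for hepatocyte, atrium and adipocyte markers in the 4 groups; each point is a gene measured in both TAC tables, lines join a gene and bars are medians. Vehicle and NR groups come from separately normalized tables. Of the 22 hepatocyte markers, 19 were at least 8-fold higher in Vehicle TAC than in both Vehicle SHAM and NR TAC.

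The fourth comparison asked what NR changed without TAC. Interferon response genes shifted down (27 of 27 negative, median −0.39, list adjusted p 3.8e-12), and immediate early genes did too (13 of 16 negative, median −0.54, list adjusted p 2.8e-10), 5 of them falling adjusted over the list alone and 0 over all genes. Extracellular matrix genes (median −0.26), heat shock genes (median −0.29) and cell cycle genes (median −0.22) shifted down, with fibroblast markers (15 of 15 negative, median −0.18, list adjusted p 0.00012) and macrophage markers (19 of 20 negative, median −0.11, list adjusted p 0.00759). The circadian clock shifted up (13 of 17 positive, median 0.34, list adjusted p 0.00115). Shisa6 (1.07), Kcnv2 (0.42) and Ube2e2 (0.46), and Ier2 (−0.61), Egr1 (−1.36) and Snai1 (−0.71), had the smallest p-values of each sign under the same limits on mean and symbol in the authors' deposited table and did not pass (DESeq adjusted p 1). Nmrk2 (−0.87, unadjusted p 0.0165), Nampt (0.28), Nppa (−0.59), Nppb (−0.74), Myh7 (0.01), Myh6 (0.10) and Dhrs7c (0.04) did not pass in the authors' deposited table. Short-chain dehydrogenases/reductases (list adjusted p 0.379) and NAD metabolism (0.119) did not pass as lists. Hepatocyte markers were mostly higher (20 of 22 positive, median 2.02, cameraPR p 3.3e-06). That list was written after its pattern had been seen in these data, so the p-value is not support for an NR effect. Only 3 of the 22 markers had a Vehicle SHAM mean of at least 50. Adipocyte markers (median −2.09, list adjusted p 0.000292) and atrial markers (median −0.82, list adjusted p 0.0006) shifted down in the same comparison.

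Over 19917 genes the authors' deposited table called 0 at a DESeq adjusted p below 0.05. An unadjusted p below 0.05 was found for 374 genes, fewer than the share of 0.05 that unchanged genes would give. For this pair too, the size of change that could be found was not simulated, so 0 calls do not show an absence of an NR effect. Lists passing numbered 14, and 10 with a preset correlation of 0.05; those lost were mitochondrial biogenesis regulators (adjusted p 0.132), macrophage (0.0543), blood (0.0995) and sex (0.0703) markers. Of 729 Reactome sets 38 passed, 36 of them down, and 10 when ranked by fold change among genes with a mean of at least 10.

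The difference of the NR effect between TAC and SHAM hearts was tested over 18474 genes, and 0 passed. An unadjusted p below 0.05 was found for 224 genes, fewer than the share of 0.05 that unchanged genes would give. Under the same limits on mean and symbol, the smallest p-values of each sign belonged to Timd4 (difference 1.57), Ifi211 (1.04) and Ifi207 (0.90), and to Cyp2c29 (−14.05), Mir22hg (−0.89) and Tspan17 (−0.77), none of which passed. Cyp2c29, a cytochrome P450 gene, had NR effects of −10.89 in TAC and 3.15 in SHAM hearts, the same signs as the hepatocyte marker medians. Nmrk2 had a difference of −1.45 and Nampt of 0.10, neither passing. On simulated data this approximate test found 2% of 2-fold and 57% of 4-fold changes, so a difference of the smaller size would mostly not be detectable. That simulation used 1 dispersion of 0.1 for all genes. In its run without changes, 5.49% of p-values from the approximate z lay below 0.05. The deposited data gave a smaller share, 224 of 18474, so the 57% need not hold and 4-fold differences may be missed too.

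Fold changes for NR in TAC hearts ran against those for TAC in vehicle hearts across 20299 genes (Pearson r −0.842, Spearman rho −0.551), where chance values of the shared Vehicle TAC libraries alone gave a simulated r of −0.488. The covariance was −0.661 against a simulated −0.192. Without the 278 genes r was −0.603 (simulated −0.488) with a covariance of −0.178 against −0.193, and with a mean of at least 50 as well r was −0.571 (simulated −0.489) with −0.067 against −0.025. Those genes were chosen by opposite changes in these 2 comparisons, so leaving them out had to weaken the relation, and no excess over the shared libraries is claimed from these values. Part of the relation may come from the shared libraries, and genes are not independent replicates.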

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

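The alternatives without the 278 genes at least 8-fold higher in Vehicle TAC than in both Vehicle SHAM and NR TAC, and the interaction taken from the TAC comparisons, were chosen after seeing the data. At an adjusted p below 0.01, 3 genes passed for TAC in vehicle hearts and 37 in NR hearts, where 40 had an absolute log2 fold change of at least 1; a stricter threshold leaves fewer by construction. Reactome sets passing with ranking by fold change among genes with a mean of at least 10 were 41 for TAC in vehicle hearts, 27 for TAC in NR hearts, 43 for NR in TAC hearts and 10 for NR in SHAM hearts, and 43 for TAC in vehicle hearts without the 278 genes; which of the ranking and the mean mattered was not tested. The correlation of the TAC effects was −0.034 with a mean of at least 50, which turned its sign although the Spearman rho rose from 0.369 to 0.593, 0.874 among called genes and 0.348 without the 278 genes. The correlation of the NR with the TAC effect was −0.603 without the 278 genes (simulated −0.488) and −0.571 with a mean of at least 50 as well (simulated −0.489), the covariance of the first being −0.178 against a simulated −0.193; both had to be nearer 0, since the genes left out were chosen by opposite changes in these comparisons. The other 61 summary values kept their side or lay within 1.5 times, or 0.1 for a correlation. Among named genes and lists, 777 values kept their side of the threshold, 39 no longer passed and 3 newly passed, and 0 reversed. The NR effect stayed at 0 calls in both surgeries under every alternative run. No adjusted p for NR lay below any threshold tried. The other thresholds, the fold minimums and the recomputed adjustment therefore had to give 0 and are no test of that count. A minimum mean could have added calls, as it did for TAC in NR hearts, but added none for NR. The interaction from the TAC comparisons gave 0 of 18774, with 158 at an unadjusted p below 0.05. No paired analysis was possible because the labels carry library numbers only and the tables hold group means. For the same reason no result is given for the following alternatives, and limma fits seen on counts solved from the means were set aside: other size factors, filters and count tests per library, fits of only 2 groups, each library left out in turn, the library-number term, other pseudocounts, an estimated correlation, a split of the Vehicle TAC libraries and other splits of the samples.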

Other observations

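All tests of explanations below, and their bounds, were chosen after the results had been seen; the bound of 0.5 and the rule for the short-chain dehydrogenase/reductase list replaced earlier ones once their values were known, as did the reading of the marker p-values from both comparisons. Beyond the lists, SUMOylation sets ranked up for NR in TAC hearts (normalized enrichment score 1.86, adjusted p 0.00236), as did assembly of the primary cilium (1.65). Chaperonin-mediated protein folding ranked up for TAC in NR hearts (2.15, adjusted p 0.000222) and down for NR in SHAM hearts (−2.37, adjusted p 1.6e-06), comparisons that share the NR SHAM libraries. Mitochondrial translation ranked down for TAC in vehicle hearts (−1.74) and in NR hearts (−2.21).

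Bmp10, a growth factor of atrial muscle, had means of 4.21 in NR SHAM and 6511 in NR TAC in the authors' deposited table (unadjusted p 0.00306), and of 1033 in Vehicle SHAM and 66.0 in Vehicle TAC in the authors' deposited table (unadjusted p 0.189). Every atrial marker was higher in NR TAC than in NR SHAM, among them Myl4 (2172 and 22190 in NR SHAM and NR TAC) and Sln (273 and 4352) in the authors' deposited table. The source of this shared rise was not tested. Ucp1, the uncoupling protein of brown fat, was listed at 0 in NR SHAM and had a mean of 146 in NR TAC in the authors' deposited table (unadjusted p 0.00218).

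Hepatocyte transcripts were high in the Vehicle TAC mean: 19 of 22 markers were at least 8-fold above both neighbouring groups, and Alb, Apoa1 (2880) and Fga (2051) were among the abundant ones in the authors' deposited table. A TAC effect on these transcripts whatever the drug is argued against by their median of −2.83 for TAC in NR hearts, where Alb had means of 111 in NR SHAM and 10.1 in NR TAC in the authors' deposited table. That median rests on 19 markers with low means in NR hearts, partly raised in NR SHAM over Vehicle SHAM (median 2.02), while Ahsg (1.93), Cyp2e1 (1.24) and Trf (0.25), with higher means there, had positive fold changes that did not pass in the authors' deposited table. Liver RNA in 1 or more Vehicle TAC libraries is left open by these 19 markers. Against Vehicle SHAM the 22 markers had log2 fold changes of 2.45 to 10.4 but unadjusted DESeq p-values of 0.0465 to 0.401. Their median p was 0.101. Such p-values at such folds imply a wide spread for these markers in that comparison. Against NR TAC the smallest p was 0.00611, 17 of 22 lay below 0.05 and 13 fell adjusted over the list alone. Read over both comparisons, the p-values therefore cannot tell whether the rise was of like size in each Vehicle TAC library. A rise in more than 1 library is not excluded. The list, the 278 genes and these tests were chosen after the pattern had been seen, first in counts per library solved from the group means and then set aside, and a biological source was not excluded.

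The lower short-chain dehydrogenase/reductase list for NR in TAC hearts may rest on the same transcripts. Without the 278 genes the list adjusted p was 0.285, its median moved from −0.11 to −0.09 and its mean z from −0.40 to −0.24. The 6 members left out were Hsd17b13, Hsd17b2, Hsd17b6, Hsd3b2, Rdh7 and Sdr9c7, with Rdh7 at 344 in Vehicle TAC and listed at 0 in NR TAC in the authors' deposited table. Those genes were chosen partly by their fall in this same comparison, so the call had to weaken, and a lower expression of the family and liver RNA cannot be told apart here.

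Fewer genes were called for TAC in vehicle hearts than in NR hearts, 10 against 115. Different responding genes are argued against, for those called in NR hearts, by the same sign in 115 of 115. Of the 10 called in vehicle hearts 6 were not called in NR hearts, and Fjx1 had the opposite sign there (2.09 against −0.42 in the authors' deposited table). Over the 115 genes the median ratio was 0.961, with quartiles of 0.674 and 1.18, so for most of them the vehicle effect was not under 0.5 times as large. The bound of 0.5 was set with these values known, so it is no test of a smaller vehicle effect. Single genes lay below it, among them Egr1 (0.08 in vehicle against 1.30 in NR hearts) and Klf4 (0.11 against 0.72) in the authors' deposited tables. A modestly smaller effect is not excluded. The difference itself had an unadjusted p below 0.05 in 4 of the 115 genes, and a larger spread between the vehicle libraries, of which there were 7 against 9, was not tested.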
